A study of Mus musculus with 7 samples.

How the data were processed

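RNA from RAW264.7 cells, a mouse macrophage-like cell line, was measured on 7 Affymetrix arrays, of which 3 were labelled wild type and 4 were labelled Gfi1 knockout. Per the labels' protocols, total RNA was isolated with TRIzol, biotinylated cRNA was prepared by the manufacturer's procedure, and the cells had received no treatment. Groups and replicate numbers were taken from the sample titles, which call the knockout arrays RAW GfI1-1 without saying whether the ending names a clone, a guide or a null genotype. The series description names Gfi1 knockout cells and 7 samples, but numbers both groups as samples 1 to 3, so the 4 knockout arrays rest on the titles. The knockout method, the edited part of the gene, and whether replicates came from separate cultures, days or clones are not given in the sources used here.

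The authors deposited 1 column of normalized signal per array for 19431 probe sets. RMA (robust multi-array average, which corrects background, quantile normalizes and summarises probes) is named in the submitters' processing notes, with no version. The deposited values were intensities on a linear scale rather than log2 values, as their range showed, so log2 was taken before any test. Median intensity per array ran from 93.8 to 101, so the columns were close in scale but not identical in distribution. Quantile normalization before deposit shares out array-wide differences, so a global rise or fall of RNA content cannot be read from these values. No detection calls and no background measurements were used here, so a low signal cannot be told from cross-hybridisation. Array data carry no read depth, and the number of arrays limits the precision.

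Probe sets were named through a platform annotation table. Of all probe sets, 17335 had 1 gene symbol, 532 had several and 1564 were unnamed. For 17297 of the single-symbol probe sets the gene number was found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. The named probe sets covered 9999 genes, of which 4479 had more than 1 probe set, and each gene was represented by its probe set with the highest mean over all 7 arrays. Probe sets with several or no symbols, 2096 in all, were left out of the gene tests. Ranks by signal, such as the lowest 5% of genes, are among the 9999 genes. Whether genes missing from the deposited table were absent from the array or left out before deposit is not known here.

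Arrays labelled knockout were compared with arrays labelled wild type by limma 3.58.1 in R 4.3.3, with a linear model of 2 groups, moderated two-sided tests and Benjamini-Hochberg adjustment over the 9999 genes. The threshold was an adjusted p of 0.05, and changes of at least 2-fold were counted as well. The fit had 5 residual and 2.20 prior degrees of freedom. Before the data were examined, 36 gene lists were fixed, and the 31 with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. The same lists were tested with an estimated correlation, by ranks, and with fry, which asks whether a list's genes move on balance one way without comparing them with other genes. Counts adjusted over the list alone use only the p-values of that list's members. Where no other test is named, the adjusted p of a list and its passing refer to camera at the preset correlation.

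The genes named were set by a rule fixed at the same time. It takes Gfi1, Gfi1b and the measured members of a list of reported Gfi1 repression targets; the 12 largest rises and 12 largest falls among genes past the threshold with all 4 knockout arrays on 1 side of all 3 wild-type arrays, leaving out model names; up to 4 members past the threshold per list by size of change, with the member of highest mean; and, for cell type lists, the member with the highest mean in each group. Genes named outside this rule are said to be chosen after their values were seen.

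Alternatives fixed before the data were examined covered quantile normalization of the deposited values, centring each array on its median, leaving out genes under the 40th percentile of mean signal, an intensity trend with a robust prior, array weights, the mean of a gene's probe sets, a test against a fold of 1.2, an unmoderated test, replicate number as a block, and leaving out each array. The array weights were estimated without full convergence. After the data were examined, 4 alternatives were added because the knockout arrays fell into 2 pairs. These averaged each pair, treated the wild-type arrays and each pair as random blocks, or left out either pair.

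The tests were tried on simulated data for the knockout against wild type comparison over 9999 genes, with all arrays independent, which the knockout pairs are not. Of 50 genes changed at each size, 46% were recovered at a log2 difference of 0.5, 86% at 1, 100% at 2 and 98% at 3, while 13 unchanged genes were called. With no knockout effect but deviations between cultures of the size seen between the knockout pairs, a median of 1849 genes was called, so the first count is not the rate of false calls for pairs of this kind. Of 200 unshifted lists of genes drawn at random, 0 were called, which gives no error rate for lists of correlated genes. The estimated correlation of the lists tested here reached 0.963, in the interferon-stimulated list, and 23 of the 34 other splits of the arrays called at least 5 lists while calling 0 genes. The groups of such splits still hold unlike shares of knockout arrays, so this count is not a rate of false calls either. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.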

Results

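Gene expression was measured in RAW264.7 cells, a macrophage-like line derived from a mouse leukaemia, to compare cells labelled as Gfi1 knockout with wild-type cells in the untreated state. Gfi1 is a zinc finger protein that represses transcription in blood cells. There were 3 wild-type arrays and 4 knockout arrays, and the signal of 9999 named genes was compared. The labels call the replicates biological without naming separate cultures or clones, so p-values measure only the spread between these arrays, which can be technical.

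The 3 wild-type arrays lay close together, with an SD of the log2 difference over all 19431 probe sets of 0.13 to 0.19 between any 2 of them. Knockout replicates 1 and 2 were as close to each other, at 0.16, and so were knockout replicates 3 and 4, at 0.14. Between these pairs the SD was 0.52 to 0.54. Replicates 1 and 2 lay 0.80 to 0.81 from the wild-type arrays, and replicates 3 and 4 lay 0.56 to 0.57 from them. Genes at least 2-fold above the wild-type mean numbered 640 and 626 in knockout replicates 1 and 2, and 292 and 285 in replicates 3 and 4. Genes at least 2-fold below it numbered 646 and 667, and 324 and 335. In each wild-type array both numbers were 0. No label separates the knockout arrays, and they were analysed as 1 group of 4.

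**Figure D1:**
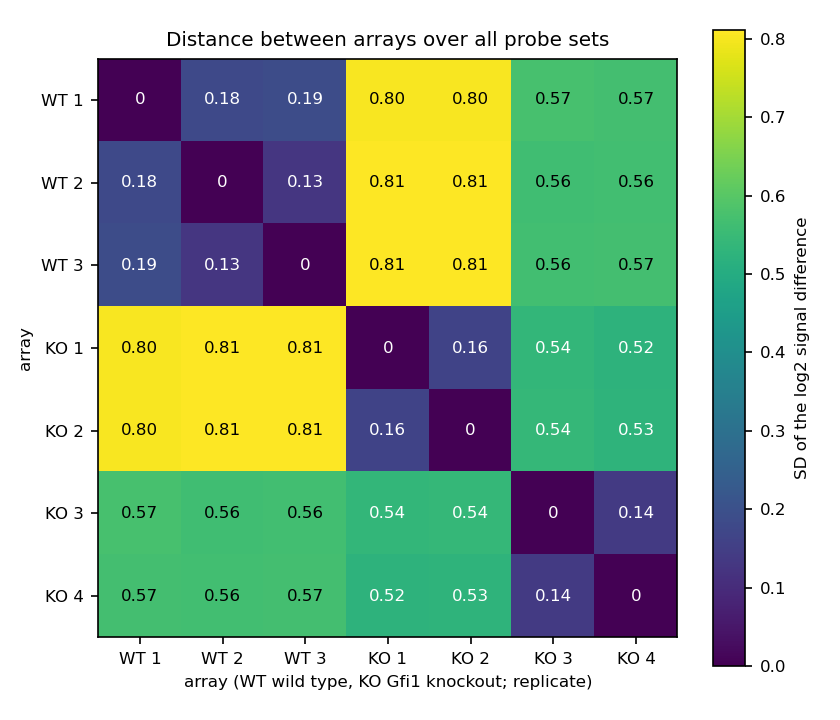
Distance between each 2 of the 7 arrays, given as the SD of the difference in log2 signal over 19431 probe sets (colour and printed value; both axes list the arrays, WT wild type and KO Gfi1 knockout with the replicate number). Knockout replicates 1 and 2 differ by 0.16 and replicates 3 and 4 by 0.14, while the pairs differ from each other by 0.52 to 0.54.

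The targeted gene was higher, not lower, in the arrays labelled knockout. The only Gfi1 probe set had a log2 signal of 2.83 ± 0.16 (SD, n = 3) in wild type and 4.47 ± 0.58 (SD, n = 4) in knockout, a difference of 1.65 (SE 0.30, limma adjusted p = 0.00447). The difference from the wild-type mean was 2.11 and 2.19 in knockout replicates 1 and 2, and 1.15 and 1.14 in replicates 3 and 4. The signal was low throughout: it exceeded that of 2.14% to 3.15% of genes in the wild-type arrays and of 7.48% to 15.1% in the knockout arrays. A probe outside the edited part of a gene need not fall in a knockout, and where this probe set lies relative to the edit is not known here, so it checks neither the labels nor the loss of the protein. All directions given here rest on the labels. Gfi1b, the close relative of Gfi1, was not among the 9999 named genes of the deposited table.

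The largest rise in the arrays labelled knockout was in Ptgs2, the inducible cyclooxygenase, from 5.08 ± 0.05 to 11.26 ± 0.71 on the log2 scale, a difference of 6.18 (SE 0.35, adjusted p = 4.15e-05). It was followed by Lcn2, an iron-siderophore binding protein (5.18, SE 0.23), and Cxcl2, a neutrophil chemokine (4.95, SE 0.29). Acod1, which makes itaconate, rose by 4.68 (SE 0.21), Nfkbiz, an inducible nuclear regulator of NF-kappaB targets, by 4.41 (SE 0.15), Il1b by 4.05 (SE 0.59) and Il6 by 3.94 (SE 1.05). The other 5 of the 12 largest rises were Urah (4.94), Phlda1 (4.72), Nxf7 (4.13), Spink5 (3.84) and Procr (3.77). Among these rises Il6 differed most between knockout arrays, at 5.80, 5.77, 1.98 and 2.20 above wild type in replicates 1 to 4.

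The largest fall was in Gpnmb, a transmembrane glycoprotein of macrophages, from 8.79 ± 0.07 to 3.69 ± 0.29 (-5.10, SE 0.16, adjusted p = 4.31e-06). The surface protein gene Cd24a (-4.92, SE 0.15), the guanylate-binding protein gene Gbp8 (-4.89, SE 0.16), the myosin gene Myo1f (-4.30, SE 0.15) and the sphingosine-1-phosphate receptor gene S1pr1 (-3.76, SE 0.10) followed. Clec10a, a lectin of macrophages and dendritic cells, fell by 3.69 (SE 0.32) and the growth factor gene Bmp2 fell by 3.15 (SE 0.08). The other 5 of the 12 largest falls were Rcbtb2 (-3.13), Selenop (-3.11), Ap1s2 (-3.06), Ms4a6c (-3.03) and the adhesion molecule gene Cadm1 (-2.80). Ms4a6c fell further in knockout replicates 3 and 4 (-4.36 and -4.54) than in replicates 1 and 2 (-1.56 and -1.68), a difference between arrays that was not tested. For some named genes the mean of 1 group lay among the lowest 5% of genes, where signal cannot be told from background, so the size of their differences and their order are uncertain. This held in wild type for Gfi1, Il6 and Nxf7, and in knockout for Cd24a, Gbp8, Myo1f, S1pr1, Bmp2, Selenop, Maf, Il7r and Pdgfrb. The limit was 3.51 in wild type and 3.49 in knockout. Urah in wild type (3.53) and Gpnmb in knockout (3.69) lay little above it, so their sizes and ranks are not secure either.

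**Figure D2:**
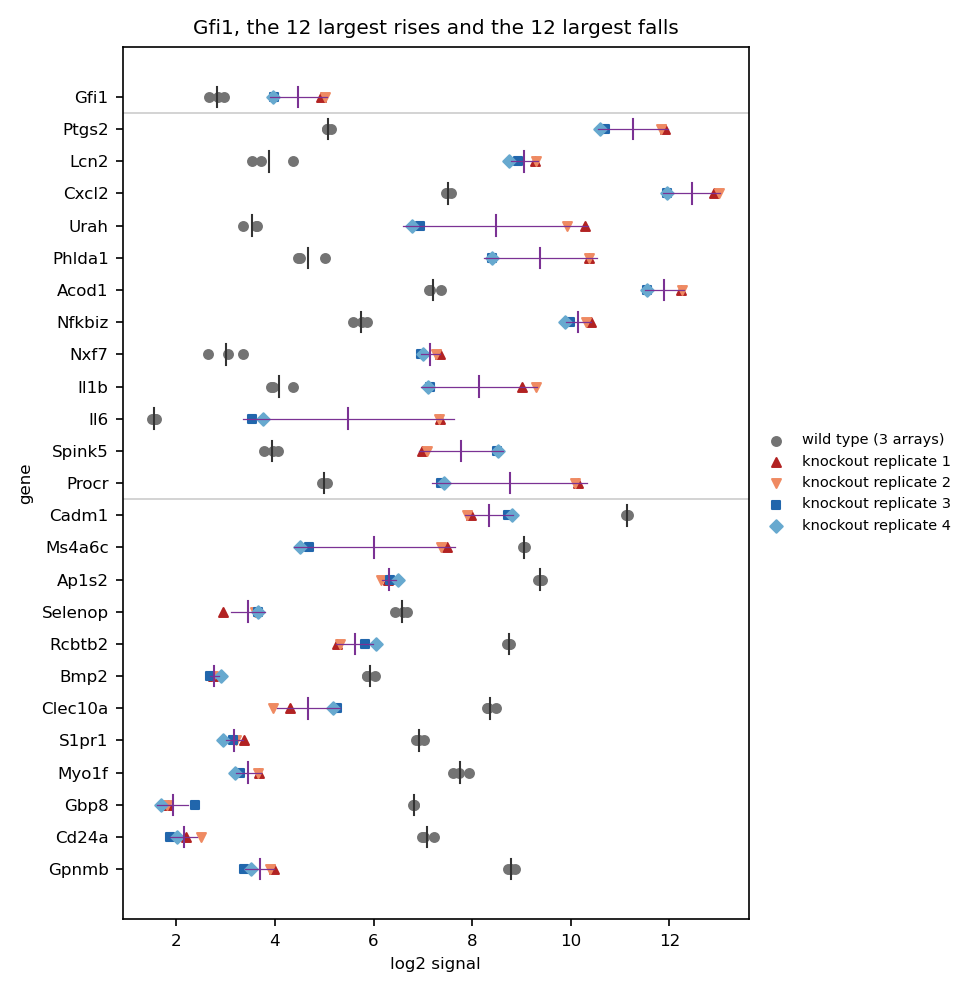
Log2 signal (horizontal axis) of Gfi1 and of the 12 largest rises and 12 largest falls (vertical axis), each point 1 array. Vertical ticks are group means (black wild type, purple knockout) and the purple bar is the knockout mean ± SD (n = 4). Ptgs2 stands at 5.08 in wild type and 11.26 in knockout, and Gpnmb at 8.79 and 3.69.

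In all, 4305 of 9999 genes passed the limma threshold, which is 43.1%, with 2149 higher and 2156 lower in knockout. By at least 2-fold, 375 were higher and 381 lower, and for all 756 of these the 4 knockout arrays lay on 1 side of the 3 wild-type arrays. Each knockout array was at least 2-fold from the wild-type mean for 224 of the higher and 213 of the lower genes. Groups did not overlap for 54.5% of all genes. For independent arrays chance would give 5.71%, but the knockout arrays formed pairs and the wild-type arrays lay close together. The rate for such arrays was not computed and can be much higher. The count depends on treating the 4 knockout arrays as independent: with the pairs of similar arrays as random blocks, a setting added after the data were seen, 904 genes passed (448 higher, 456 lower), and without replicates 3 and 4, 6814 passed (626 higher and 655 lower by 2-fold). Simulated data with no knockout effect, but cultures deviating as the pairs did, gave a median of 444 genes with such blocks. Passing with the blocks therefore does not secure a gene as changed by the knockout. The SE and adjusted p of single genes also treat the arrays as independent: with those blocks, Gfi1 and 84 of 128 other named genes still passed, while 44 did not (adjusted p from 0.0503 to 0.536). Among the largest changes these were Il6 and Ms4a6c. The others were Cxcl10, Usp18, Traf1, Dusp5, Tlr3, Irak2, Cd86, Nlrc5, C3ar1, Cr1l, C5ar1, Bst2, Gas6, Cyp51, Nceh1, Scd1, Sdhc, Ndufa9, Ndufb5, Eno2, Pdk1, Kif11, Birc5, Top2a, Pcna, Ccng1, Atf3, Ddit3, Ankrd37, Rpl12, H1f2, Cbx5, Phf21a, Prmt1, Il7r, Mitf, Bank1, Hba-a2, Tfrc, Lmo2, Tal1 and Mycn. The number of genes called was 1746 when tested against a fold of 1.2, 194 and 191 by 2-fold when dim genes were left out, and 1379 or 1404 higher genes without wild type replicate 2 or 3.

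Inflammatory gene lists were higher in knockout. Of 24 inflammatory cytokine and chemokine genes, 14 rose and 2 fell (16 and 2 adjusted over the list alone), with a median log2 difference of 1.84 and a camera adjusted p of 0.00163 (adjusted p = 0.682 with an estimated correlation). Besides Ptgs2, Cxcl2, Il1b and Il6, the chemokine gene Ccl9 had a difference of -0.09 (SE 0.18, adjusted p = 0.727). Of 21 NF-kappaB pathway and feedback genes, 14 rose and 0 fell (15 and 0 adjusted over the list alone; median 0.76, adjusted p = 6.42e-06, and adjusted p = 0.554 with an estimated correlation). Next to Nfkbiz, the subunit gene Rel rose by 3.39 (SE 0.66), the adaptor gene Traf1 by 2.88 (SE 0.68), the receptor gene Cd40 by 1.78 (SE 0.16) and the inhibitor gene Nfkbia by 0.72 (SE 0.05). Of 25 immediate early and MAPK feedback genes, 16 rose and 2 fell, the same adjusted over the list alone (median 0.77, adjusted p = 0.00146; adjusted p = 0.554 with an estimated correlation). Ier3 rose by 3.46 (SE 0.28), the nuclear receptor gene Nr4a1 by 2.74 (SE 0.57), the phosphatase gene Dusp5 by 2.63 (SE 0.74) and the AP-1 gene Fosl1 by 2.53 (SE 0.24), and Jund by 0.49 (SE 0.12).

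Of 22 interferon-stimulated genes, 10 rose and 0 fell, the same adjusted over the list alone (median 1.27, adjusted p = 0.00124; adjusted p = 0.745 with an estimated correlation and 0.0755 with fry). Cxcl10 rose by 2.89 (SE 0.92), Xaf1 by 2.27 (SE 0.40), the transcription factor gene Irf7 by 1.97 (SE 0.41), Usp18 by 1.65 (SE 0.47) and Ifitm3 by 0.29 (SE 0.07). The list's median was 2.05 and 1.96 in knockout replicates 1 and 2, and 0.42 and 0.45 in replicates 3 and 4. A group of 11 genes with symbols of Ifi and a number, looked at after the data were seen, went both ways. Of these 3 rose and 3 fell, with medians of 0.97, 0.90, -0.47 and -0.38 in knockout replicates 1 to 4 (camera adjusted p = 0.954). For the cytokine and chemokine list the medians were 2.63, 2.43, 1.27 and 1.24, for the NF-kappaB list 0.91, 1.01, 0.66 and 0.65, and for the immediate early list 1.06, 1.00, 0.65 and 0.61. The lists of receptors and of antigen display did not pass the test. Of 24 Toll-like receptor and inflammasome genes 7 rose and 7 fell, also when adjusted over the list alone (median -0.08, adjusted p = 0.788), with Tlr13 at -1.59 (SE 0.08), Tlr3 at -0.98 (SE 0.31), Aim2 at 0.97 (SE 0.07) and Irak2 at 0.93 (SE 0.26). Cd14 had a difference of 0.29 (SE 0.18, adjusted p = 0.232). Of 16 antigen presentation genes 3 rose and 5 fell, also over the list alone (median -0.15, adjusted p = 0.788), with H2-DMa at -1.63 (SE 0.15), Cd86 at -1.35 (SE 0.35) and Nlrc5 at 0.76 (SE 0.21), while B2m stood at -0.17 (SE 0.06, adjusted p = 0.0683). The antigen presentation medians were 0.26, 0.24, -0.41 and -0.45 in knockout replicates 1 to 4, so the 2 pairs went opposite ways. Of 8 complement genes 1 rose (C5ar1, 0.23, SE 0.07) and 2 fell (C3ar1, -1.05, SE 0.16, and Cr1l, -0.47, SE 0.13), again also over the list alone (adjusted p = 0.604).

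**Figure D3:**
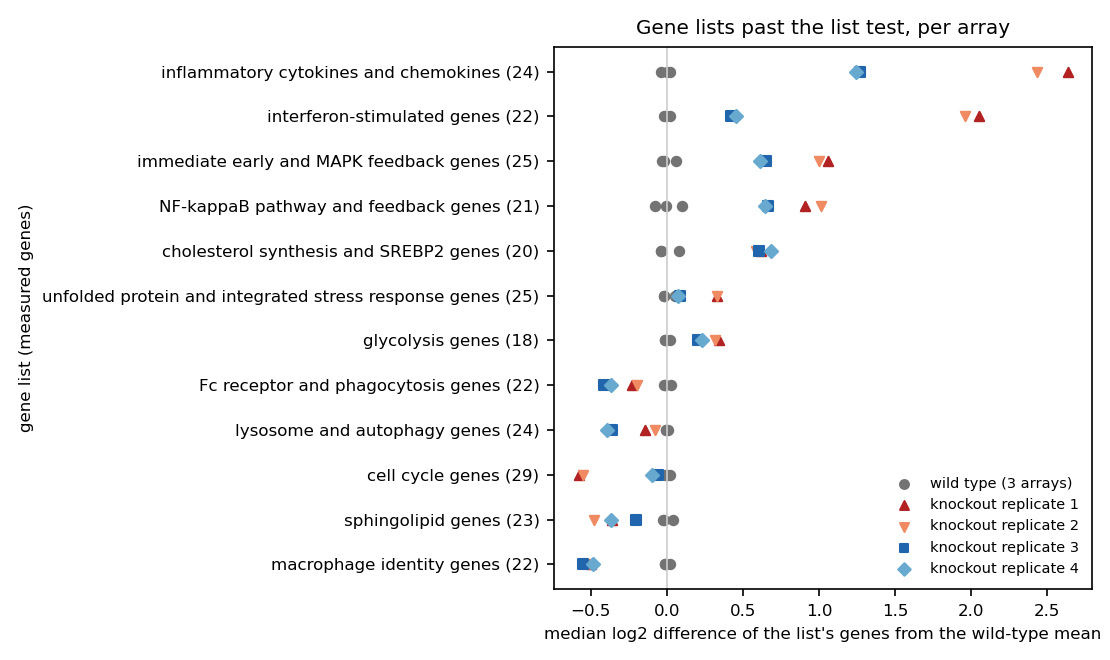
Median log2 difference from the wild-type mean (horizontal axis) of the genes in each of the 12 lists past the list test (vertical axis, measured genes in brackets), each point 1 array. The interferon-stimulated list lies at 2.05 and 1.96 in knockout replicates 1 and 2 and at 0.42 and 0.45 in replicates 3 and 4, and cholesterol synthesis lies between 0.58 and 0.68 in all 4.

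Macrophage genes were lower in knockout. Of 22 macrophage identity genes 14 fell and 4 rose, the same adjusted over the list alone (median -0.51, adjusted p = 0.00124; adjusted p = 0.346 with an estimated correlation). The Fc receptor gene Fcgr3 fell by 2.23 (SE 0.20), the chemokine receptor gene Cx3cr1 by 2.16 (SE 0.12) and the pore-forming protein gene Mpeg1 by 2.03 (SE 0.17). The transcription factor gene Maf fell by 2.77 (SE 0.14), to a signal too low for its size to be certain. The lysozyme gene Lyz2 fell by 0.45 (SE 0.08). Of 22 Fc receptor and phagocytosis genes 11 fell and 2 rose, the same adjusted over the list alone (median -0.21, adjusted p = 0.0145; adjusted p = 0.554 with an estimated correlation). The receptor gene Trem2 fell by 2.78 (SE 0.40), the bridging ligand gene Gas6 by 1.93 (SE 0.39), the beta-glucan receptor gene Clec7a by 1.88 (SE 0.07) and the adaptor gene Tyrobp by 0.92 (SE 0.06). Of 24 lysosome and autophagy genes 11 fell and 1 rose (11 and 3 adjusted over the list alone; median -0.26, adjusted p = 0.00804; adjusted p = 0.554 with an estimated correlation). The protease gene Ctsd fell by 1.26 (SE 0.06), Hexa by 0.95 (SE 0.09), the lipase gene Lipa by 0.91 (SE 0.06), Ctsa by 0.72 (SE 0.06) and Ctss by 0.57 (SE 0.06). Medians in knockout replicates 1 to 4 were -0.50, -0.52, -0.55 and -0.49 for macrophage identity, -0.23, -0.20, -0.41 and -0.36 for phagocytosis genes, and -0.14, -0.08, -0.36 and -0.40 for lysosome genes. Without replicates 3 and 4, the identity, phagocytosis and lysosome lists no longer passed, at adjusted p = 0.0953, 0.187 and 0.272, and the lysosome list did not pass with a replicate block (0.0516). Of 9 alternative activation genes 6 fell and 3 rose, also over the list alone (median -1.12, camera adjusted p = 0.0908, and 0.000286 downwards with fry). Among them were Tgm2 (-1.91, SE 0.21), Klf4 (-1.43, SE 0.19) and Stat6 (-0.59, SE 0.09).

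Lipid genes moved in both directions. Of 20 cholesterol synthesis and SREBP2 genes 14 rose and 1 fell (15 and 1 adjusted over the list alone; median 0.57, adjusted p = 5.57e-05; adjusted p = 0.346 with an estimated correlation), and the list's median lay between 0.58 and 0.68 in each knockout array. The lanosterol synthase gene Lss rose by 1.22 (SE 0.12), the sterol-sensing transcription factor gene Srebf2 by 1.13 (SE 0.15), the squalene synthase gene Fdft1 by 1.02 (SE 0.08), Cyp51 by 0.94 (SE 0.13) and Fdps by 0.91 (SE 0.12). Of 23 sphingolipid genes 12 fell and 1 rose, the same adjusted over the list alone (median -0.41, adjusted p = 0.00146; adjusted p = 0.346 with an estimated correlation). Next to S1pr1, the ceramide kinase gene Cerk fell by 2.42 (SE 0.18), Galc by 0.92 (SE 0.14) and the acid ceramidase gene Asah1 by 0.48 (SE 0.06), while the ceramide synthase gene Cers4 rose by 1.51 (SE 0.12). The list medians were -0.36, -0.48, -0.20 and -0.37 in the 4 knockout arrays.

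Of 14 eicosanoid genes 7 fell and 2 rose, also over the list alone, and the list did not pass with camera (median -0.26, adjusted p = 0.103, and 0.000286 downwards with fry). Ptgs2 rose as given, while Hpgd, which inactivates prostaglandins, fell by 2.12 (SE 0.07), the leukotriene receptor gene Cysltr1 by 1.42 (SE 0.18) and Alox5ap, needed for leukotriene synthesis, by 1.35 (SE 0.07). Of 26 fatty acid and triglyceride genes 7 rose and 1 fell, also over the list alone (median 0.07, camera adjusted p = 0.190, and 0.000497 upwards with fry). The fatty acid binding protein gene Fabp5 stood at 2.77 (SE 0.08), Me1 at 1.34 (SE 0.08), Lpin1 at 0.94 (SE 0.09) and the lipid droplet coat gene Plin2 at -1.22 (SE 0.06). Of 15 LXR target and cholesterol efflux genes 3 rose and 4 fell (5 and 5 adjusted over the list alone). The list's adjusted p was 0.741 with camera and 0.0445 downwards with fry. Pltp fell by 2.06 (SE 0.11), Lpl by 0.89 (SE 0.07) and Nceh1 by 0.78 (SE 0.14), Scd1 rose by 0.70 (SE 0.20), and Npc2 had a difference of -0.27 (SE 0.14, adjusted p = 0.153).

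Of 18 glycolysis genes 10 rose and 2 fell, the same adjusted over the list alone (median 0.25, adjusted p = 0.0168; adjusted p = 0.346 with an estimated correlation). The enolase gene Eno2 rose by 1.61 (SE 0.42), Pfkp by 0.94 (SE 0.06), the glucose transporter gene Slc2a1 by 0.88 (SE 0.10) and Pgk1 by 0.23 (SE 0.06), and Pdk1 fell 2.29-fold (adjusted p = 0.0390). The list median was 0.34, 0.31, 0.20 and 0.23 in knockout replicates 1 to 4. The call ended when dim genes were left out (adjusted p = 0.0548), with a replicate block (0.0516) and without knockout replicates 3 and 4 (adjusted p = 0.167). Of 29 oxidative phosphorylation genes 10 fell and 1 rose (8 and 1 adjusted over the list alone), with a median of -0.09. This list did not pass with camera (adjusted p = 0.0542), but passed downwards by ranks (adjusted p = 0.0423) and with fry (adjusted p = 0.000896). Sdha stood at -0.62 (SE 0.08), Sdhc at -0.49 (SE 0.09), Ndufa9 at -0.34 (SE 0.07), Ndufb5 at -0.33 (SE 0.06) and Cox5b at -0.07 (SE 0.05, adjusted p = 0.292).

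Of 25 unfolded protein and integrated stress response genes 9 rose and 2 fell, the same adjusted over the list alone (median 0.25, adjusted p = 0.0168; adjusted p = 0.682 with an estimated correlation). The cystine transporter gene Slc7a11 rose by 3.32 (SE 0.37), Ppp1r15a by 1.78 (SE 0.35), Atf3 by 1.41 (SE 0.44), Ddit3 by 0.95 (SE 0.21) and the chaperone gene Hspa5 by 0.66 (SE 0.18). The list median was 0.33 in knockout replicates 1 and 2, and 0.08 and 0.07 in replicates 3 and 4, and without replicates 1 and 2 the list did not pass (adjusted p = 0.132). Cell cycle genes as a list were lower in knockout: 4 of 29 fell and 1 rose (1 and 0 adjusted over the list alone; median -0.34, adjusted p = 0.0361; adjusted p = 0.891 with an estimated correlation). Their medians were -0.58, -0.55, -0.06 and -0.10 in the 4 knockout arrays, and the call ended without replicates 1 and 2 (adjusted p = 0.725), without replicate 1 (0.136) or 2 (0.129), without wild type replicate 3 (0.0674) and with array weights (0.0503), probe set means (0.0540) or fry (0.216). Kif11 fell 2.30-fold (adjusted p = 0.0389), Birc5 by 0.63 (SE 0.20), Top2a by 0.62 (SE 0.19) and Pcna by 0.35 (SE 0.05).

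Other functional lists did not pass with camera. With fry, the ribosomal protein list (adjusted p = 0.000403) and the histone list (adjusted p = 0.00955) passed downwards. Of 20 Nrf2 and heme response genes 6 rose and 8 fell, also over the list alone (adjusted p = 0.994), with Blvrb at 1.43 (SE 0.12), Slc40a1 at 1.19 (SE 0.07), Gpx1 at -0.90 (SE 0.10) and Fth1 at 0.04 (SE 0.10, adjusted p = 0.761). Of 20 p53 target and apoptosis genes 4 rose and 4 fell, also over the list alone (adjusted p = 0.994), with Trp53inp1 at -2.34 (SE 0.35), Bcl2l1 at 1.64 (SE 0.24), Pmaip1 at 0.94 (SE 0.10), Mcl1 at 0.14 (SE 0.12, adjusted p = 0.342) and Ccng1 at -1.16 (SE 0.34), for which another probe set was called in the opposite direction. Of 19 hypoxia response genes 7 rose and 7 fell, also over the list alone (adjusted p = 0.788), with Egln3 at -2.32 (SE 0.11), Ankrd37 at -1.88 (SE 0.50), Ero1a at 1.78 (SE 0.20) and Ldha at 0.09 (SE 0.06, adjusted p = 0.303). Of 24 cytosolic ribosomal protein genes 1 rose and 2 fell (0 and 2 adjusted over the list alone; adjusted p = 0.519), with Rps6 at -1.33 (SE 0.06), Rpl14 at -0.84 (SE 0.06), Rpl12 at 0.30 (SE 0.09) and Rplp2 at 0.03 (SE 0.06, adjusted p = 0.673). Of 6 histone genes 0 rose and 1, H1f2, fell by 0.41 (SE 0.09), also over the list alone (adjusted p = 0.381), and H2az1 had a difference of -0.50 (SE 0.27, adjusted p = 0.176). The median, the mean and the test differed in sign for the LXR, hypoxia, p53, corepressor partner, erythroid, osteoclast and dendritic cell lists.

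Genes reported as repressed by Gfi1 went both ways. Of 21 measured, 9 rose and 5 fell, also over the list alone, with a median of 0.42 (camera adjusted p = 0.122, and 0.000403 upwards with fry). The list's median was 0.43, 0.47, 0.23 and 0.10 in knockout replicates 1 to 4. Besides Gfi1 itself, Id1 rose by 2.59 (SE 0.35), Socs3 by 2.40 (SE 0.06), Id3 by 1.63 (SE 0.08), Myc by 1.31 (SE 0.18), Egr1 by 0.75 (SE 0.08), E2f5 by 0.68 (SE 0.10), Nlrp3 by 0.57 (SE 0.07) and Cdkn1b by 0.42 (SE 0.07). Cebpa fell by 1.49 (SE 0.20), Il7r by 0.94 (SE 0.12), Csf1r by 0.60 (SE 0.06), Cdk4 by 0.54 (SE 0.07) and Spi1 by 0.43 (SE 0.07). The rest did not pass, with adjusted p from 0.205 to 0.987: Id2 stood at 1.07 (SE 0.78), with 2.45, 2.43, -0.22 and -0.38 in the 4 knockout arrays, Csf1 at 0.54 (SE 0.32), Egr2 at 0.14 (SE 0.16), Irf8 at 0.06 (SE 0.12), Cdkn1a at 0.04 (SE 0.06), Rela at 0.00 (SE 0.09) and E2f6 at -0.07 (SE 0.07). Of 17 corepressor partners of Gfi1 3 rose and 5 fell, also over the list alone (adjusted p = 0.966), with Ajuba at -1.34 (SE 0.18), Cbx5 at -0.96 (SE 0.18), Phf21a at 0.63 (SE 0.17) and Prmt1 at 0.53 (SE 0.06).

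Markers of other cell types gave no list past the camera test, while fry called the blood stem and progenitor list downwards (adjusted p = 0.0352). Of 10 osteoclast genes 2 rose and 3 fell, also over the list alone (adjusted p = 0.802): the carbonic anhydrase gene Car2 rose by 2.82 (SE 0.08), while Atp6v0d2 fell by 1.62 (SE 0.08), Nfatc1 by 0.72 (SE 0.10) and Mitf by 0.57 (SE 0.15). Of 6 dendritic cell genes 2 rose, Bst2 by 1.01 (SE 0.24) and Tcf4 by 0.77 (SE 0.13), and 1, Clec10a, fell. Adjusted over the list alone 3 rose and 2 fell, and the list's camera adjusted p was 0.815. Only 2 of 6 Tcf4 probe sets were called, both upwards. For Nfatc1 only 1 of 4 probe sets was called and for Mitf 1 of 2, each downwards. Of 6 erythroid and megakaryocyte genes 1 rose, Tfrc by 0.31 (SE 0.09), and 2 fell, Pf4 by 1.74 (SE 0.38) and Hba-a2 by 0.68 (SE 0.10), also over the list alone (adjusted p = 0.788). Of 6 blood stem and progenitor genes 1 rose and 2 fell, also over the list alone (adjusted p = 0.741): Lmo2 fell by 0.55 (SE 0.06) and Tal1 by 0.34 (SE 0.10), and Mycn, at 13.24 in wild type, rose by 0.17 (SE 0.05), although another of its probe sets was called in the opposite direction and the mean of its probe sets differed by -0.08. The deposited table held too few members of the other 5 cell type lists to test them, for instance 2 of 24 granulocyte genes and 1 of 16 fibroblast and endothelial genes. Nothing can be said here of the members it lacked. Lcn2 rose among granulocyte genes, with Csf3r at -0.39 (SE 0.15, adjusted p = 0.0727). Among B cell genes Bank1 fell by 1.97 (SE 0.28) and Ighm differed by -0.02 (SE 0.21, adjusted p = 0.940). Among T and NK cell genes Il7r fell as given, and Prf1 differed by 0.26 (SE 0.11, adjusted p = 0.0915). The mast cell gene Gata2 differed by -0.04 (SE 0.15, adjusted p = 0.864), and the fibroblast gene Pdgfrb fell by 1.19 (SE 0.09).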

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

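Far arrays were searched for among the 4 knockout arrays in 202 gene and list values. For independent arrays chance flags about 1 in 20, or 10.1 values. The knockout arrays formed pairs, so 10.1 is not the number expected for them. A far array was found in 3 values. All 3 concern knockout replicate 1 and genes that fell. Selenop lay 3.62 below the wild-type mean there, against 2.91 to 2.98 below it in the other arrays, and its gap to the nearest array was 0.896 of the whole range. For Pltp the gap was 0.866 of the range, with -1.76 in replicate 1 and -2.13 to -2.19 in the others. For Hpgd it was 0.835, with -1.98 in replicate 1 and -2.14 to -2.18 in the others. In each case all 4 arrays lay below the wild-type arrays.

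Probe sets with several or no gene symbols were outside the comparison of genes. Of 2096 such probe sets, 626 passed the limma threshold when all probe sets were tested, which is 29.9%, with 289 higher and 337 lower in knockout.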

How the results depend on the processing

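The pair averages, the random blocks and the omission of either pair of knockout arrays were chosen after the data were seen; the other alternatives were planned. Of the 4305 genes called, 904 also passed with the random blocks (448 higher, 456 lower; correlation within blocks 0.794), 3004 of the 3009 called with each pair averaged were among the 4305, and 5697 passed without knockout replicates 1 and 2. Without replicates 3 and 4, 6814 passed (3406 higher, 3408 lower), with 626 higher and 655 lower by 2-fold. Leaving out a pair removes the difference between the pairs from the spread used by the test, and only 2 close knockout arrays remain. Replicates 1 and 2 also lay farther from the wild-type arrays than replicates 3 and 4. How much each adds to these shifts was not tested. Tested against a fold of 1.2, 1746 passed (853 higher, 893 lower), because the test asks for more than a difference from 0. Leaving out dim genes left 5999 genes and 194 higher and 191 lower by 2-fold, since 4000 genes were no longer tested. Leaving out 1 array gave 1379 to 2182 higher genes, lowest without wild type replicate 2 and next lowest without replicate 3 (1404). Without wild type replicate 1, which leaves as many arrays, 1768 genes were higher, so fewer arrays alone do not account for the low counts. Other scalings changed the median of all genes by less than 0.1. The number of lists past the camera test was 12, with 13 by ranks and 0 with an estimated correlation (4 at an unadjusted p under 0.05). With fry it was 19, but its directional test does not compare a list with other genes. The estimated correlation was itself taken from residuals that hold the difference between the knockout pairs. With each list's own alternatives, 212 of 240 list results kept direction and side of the threshold and 28 lost the threshold. The 129 named genes followed were Gfi1 and the largest rises, largest falls and list examples that passed. For these, 2283 of 2517 gene results kept both and 233 lost the threshold. The random blocks gave 44 of the losses, ending the call of 34.4% of 128 named genes besides Gfi1. With the mean of a gene's probe sets 7 lost it. For Rcbtb2 and Cbx5, 2 of 4 probe sets were called, in the direction given. Only 1 result reversed: Mycn, at -0.078 with the mean of its probe sets, which include 1 called in the opposite direction. The Gfi1 rise kept its side of the threshold in each alternative that tested it, between 1.14 and 2.15, and leaving out dim genes removed it from the test. Whether replicate numbers pair the arrays could not be told. Deviations from the group means of same-numbered arrays correlated across genes at 0.12, -0.09 and 0.11, and not every array correlated best with its own number. The knockout deviations hold the difference between the knockout pairs, so this check can miss a shared culture or day. With a replicate block 3805 genes passed. In simulated data with no knockout effect, where 3 cultures deviated independently by the size seen between the knockout pairs, a median of 1849 genes passed (highest 1987 in 50 draws), with a median of 262 by 2-fold, and a median of 444 passed with random blocks, run in 10 of the draws. The covariance across genes of the log2 differences of replicates 1 and 2 and of replicates 3 and 4, which share the wild-type arrays, was 0.328, against a median of 0.123 and a highest value of 0.150 in those draws. Low signals, with no measured background, limit what can be said of genes such as Gfi1.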

Other observations

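The gene families and genes named here, and all tests of explanations except the counts of other splits, were chosen after the values were seen, so the tests of the families are not independent evidence. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, were higher in knockout: 15 of 19 rose and 0 fell, with a median log2 difference of 0.42 (camera adjusted p = 6.69e-06 over 6 such families; adjusted p = 0.103 with an estimated correlation). The list's median was 0.50, 0.44, 0.39 and 0.39 in knockout replicates 1 to 4. Cars rose by 0.91 (SE 0.16), Hars by 0.79 (SE 0.06) and Tars by 0.77 (SE 0.07). Of 38 genes with symbols starting Psma, Psmb, Psmc or Psmd, the proteasome list, 17 rose and 3 fell (median 0.20, adjusted p = 0.00421, and 0.253 with an estimated correlation). The array medians were 0.25, 0.25, 0.15 and 0.15. Families here were drawn by symbol, so not every member need belong to the family by function. Of 8 TNF receptor superfamily genes with symbols starting Tnfrsf, which leaves out Cd40, 6 rose and 0 fell (median 0.82, adjusted p = 0.0143, and 0.274 with an estimated correlation), but the array medians were 1.22, 1.16, 0.58 and 0.30. Among them were Tnfrsf13b at 2.29 (SE 0.14) and Tnfrsf9 at 2.27 (SE 0.20), with wild-type signals among the lowest 5% of genes, so that these sizes are uncertain.

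Of 5 CD300 receptor genes 4 fell and 0 rose (median -1.17, adjusted p = 0.00540; adjusted p = 0.185 with an estimated correlation), with array medians of -1.02, -0.92, -1.46 and -1.25, Cd300a at -2.38 (SE 0.14) and Cd300c2 at -1.54 (SE 0.22). Of 11 genes with symbols starting Clec, the C-type lectin list, 5 fell and 2 rose (median -0.39, with -0.16, -0.22, -0.63 and -0.68 in the 4 arrays). The list's adjusted p was 0.0428 with camera and 0.253 with an estimated correlation. Clec4a2 fell by 2.57 (SE 0.10), to a signal among the lowest 5% of genes, and Clec4a3 by 2.37 (SE 0.23), while Clec4d rose by 0.71 (SE 0.13) and Clec4e by 1.25 (SE 0.33). Of 6 MS4A family genes 3 fell and 0 rose, and the family did not pass (median -1.61, with -0.43, -0.55, -2.28 and -2.32 in the 4 arrays; adjusted p = 0.0667). Of the 3, Ms4a4b had signals among the lowest 5% of genes in both groups, so its direction cannot be read; the same held for Ms4a4c, and in knockout for Ms4a3, which did not pass. The family medians kept their sign under quantile normalization and array centring. Among all 280 families defined by a shared start of the gene symbol with 5 to 60 members, camera called 0 after adjustment and 27 at an unadjusted p under 0.05. The same 8 Tnfrsf genes and 11 Clec genes were among these families. Over all 280 their camera adjusted p was 0.334 and 0.416, so their passing above rests on adjustment over only 6 chosen families.

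Of the 35 splits of the 7 arrays into 3 and 4, only the real one gave 4305 genes, and the highest of the others gave 0 with limma (at most 3992 at an unadjusted p under 0.05, with knockout replicates 1, 2 and 4 against the rest). The real split also gave the most lists, 12, against at most 9 in the others, where wild type replicate 1 was grouped with knockout replicates 3 and 4, so 1 of the 35 splits reached either value. This excludes chance only for arrays taken as exchangeable, which the pairs of knockout arrays are not, and with each pair as 1 unit the splits would be too few to exclude it.

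The 4 knockout arrays formed 2 pairs, replicates 1 and 2 and replicates 3 and 4. Wild-type cells mixed into cultures 3 and 4 would hold each gene between the other arrays only under a condition. The knockout cells there would have to be like those of replicates 1 and 2. In 40 genes, 27 below and 13 above, replicates 3 and 4 both lay over 1 log2 unit outside the range of the other 5 arrays, for instance Rgs2 by -3.59. By contrast, 0 genes put a wild-type array as far outside the other wild-type arrays. This argues against mixing only under that condition, and wild-type cells mixed into a different knockout population stay open. For array-wide signal differences, 441 to 478 genes were 2-fold apart between the pairs after a further quantile normalization, against 3 and 2 within them. RMA already holds this step, so repeating it could change little. The values argue only against differences in the overall distribution of signal, and technical effects on single probe sets were not tested. For both tests first bounds of over 50 and over 500 genes were missed and were replaced, once the counts were seen, by these measured references. Cell populations of different chromosome content may separate the pairs: over 81 neighbouring genes of chromosome 9 (order from GRCm38.p6) the median was -0.38 and -0.41 in replicates 1 and 2, beyond all 200 shuffled gene orders, and 0.07 and 0.04 in replicates 3 and 4, but with 41 genes, the window tried first, 1 shuffled order exceeded replicate 1 (-0.51), so this stays open, as do separate clones, passages or days.

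Inflammatory genes were higher in knockout cultures labelled as untreated. An immune stimulus that reached these cultures could give the same rise, since the cytokine and chemokine list had a median of at least 1.24 in every knockout array, and culture and genotype cannot be told apart here. Relief of direct repression by Gfi1 is a possible explanation too, but the reported targets went both ways. The list's adjusted p was 0.122 with camera and 0.000403 upwards with fry, which neither excludes this explanation nor singles it out.

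The Gfi1 probe set was higher in knockout. Noise of a dim probe set stays open: the lowest knockout array lay 6.20 wild-type SD above the highest wild-type array and 3.01% of the 299 genes within 0.5 of its wild-type level rose as much, but so low a signal excludes nothing; by the bounds first set, 3 SD and 5%, noise would have been excluded, and the condition on signal level was added after these values were seen. Exchanged group labels would give the same difference of 1.65 with its sign turned, and loss of repression of Gfi1 by its own protein could raise a transcript in every knockout array, the smallest rise being 1.14. These explanations cannot be told apart without a probe whose place relative to the edit is known, and cross-hybridisation was not tested.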
